A study of Mus musculus with 4 samples.

How the data were processed

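The samples were 4 RNA sequencing libraries, 2 from Fmr1 knockout mice and 2 from wild type littermates on a C57BL/6 background. Per the labels' protocols, the dentate gyrus of mice aged 6 to 7 weeks was dissociated and 10000 living cells per sample were collected by fluorescence-activated sorting. The protocol text covers a sort of all living cells and a sort of Dcx-DsRed positive cells, while the series design names the Dcx-DsRed cells, so the libraries are described here as the latter. The labels describe poly(A)-selected, strand-specific libraries from a kit for very low RNA input, sequenced as read pairs. They do not say whether the 2 replicates of a genotype came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. They also do not name the knockout allele.

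The authors deposited 1 table of raw counts per gene, with 1 column of whole-number counts for each library. Reads were aligned to GRCm38 with STAR 2.5.3a, per the submitters' processing notes, using a Gencode annotation per the labels' protocols. The annotation release, the counting program and its strand setting are not given in the sources used here, so counts of overlapping or antisense genes, of close paralogs and of repeat-like loci are uncertain. The deposited table also holds the length of each gene in bases, used here only in a check of length and GC content. The table has 52636 genes and 0 further columns of per-sample values. Gene positions came from GENCODE M21 on GRCm38, in which 99.56% of the genes were found. That release was chosen here and is not known to be the authors' own.

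Totals ran from 5478224 to 7213759 counts per library, and 17797, 18508, 17090 and 16103 genes had at least 1 count in wild type replicates 1 and 2 and knockout replicates 1 and 2. Protein-coding genes took 86.7%, 84.1%, 86.0% and 82.6% of the counts in the same order, and mitochondrial rRNA took 1.19%, 3.32%, 1.32% and 4.57%. The locus Gm42418, which resembles nuclear rRNA, took 6.38% to 7.27%.

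Counts were filtered with filterByExpr, which kept 14673 genes, scaled by the TMM method and compared with edgeR 4.0.16 (R 4.3.3) using estimateDisp, glmQLFit with robust estimation and the two-sided quasi-likelihood F-test, with genotype as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the size of the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, with the SD over the 2 libraries of a genotype. The median log2 fold change over all genes was 0.02. The interval for P2ry2 is an exact 95% interval for a ratio of counts, and reads without molecular identifiers are not independent molecules, so it covers counting error only.

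The choice of genes, lists, tests and most alternatives was made before the data were examined. Named are Fmr1, Htt, Mfn1, Mfn2 and Opa1 whatever their result, and the 8 genes with the smallest p in each direction among called genes that separate the genotypes. With under 10 genes called, the rule instead took the 8 smallest unadjusted p values per direction among all genes that separate the genotypes. In such genes the knockout libraries both lie on one side of both wild type libraries. Clone and prediction symbols were left out, and these genes are said to be not called. For each list without a called member the rule named its member with the highest mean CPM. Some genes that the rule takes are not reported here. Examples outside the rule are said to be chosen after their values were seen.

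Gene lists were written from general knowledge as 41 sets with 945 genes, all found in the table, covering mitochondrial, metabolic, translational, synaptic, developmental, cell type and cell state genes. Lists with at least 5 tested members, 39 in all, were tested on log2 CPM (prior count of 2) with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, directional and mixed, were run beside it. Some genes stand in more than 1 list, and several glial and neuronal markers are expressed by more than 1 cell type.

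Alternatives covered other scalings (DESeq2 size factors, library size, upper quartile), other filters, DESeq2 1.42.0 and limma voom in place of edgeR, non-robust estimation, an adjusted p under 0.1, a minimum fold of 1.5, the replicate number as a block, leaving out each library in turn, leaving out mitochondrial genes, a loess on gene length and GC content, and camera on ranks. GC content was known for 99.8% of tested genes. Leaving out rRNA-like loci, the block together with the length and GC correction, and leaving out each library with the list correlation estimated were added after the data were seen.

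The gene test was tested on simulated counts for the 14673 genes with 200 changed genes. The changed genes were drawn only from those with higher expected counts. In this and in the list simulation below, genes varied independently, with no effect of replicate number. At the fitted spread it called 0 of 200 genes changed 2-fold, 47.5% changed 4-fold and 74.5% changed 8-fold, with 0, 12 and 13 unchanged genes called. At a low spread it called 94% to 100%. In simulated data the complex I list had an adjusted p of 0.663 when its members were lowered by 0.25 on the log2 scale and of 0.000283 when lowered by 0.5.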

Results

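Gene expression was measured by RNA sequencing in cells sorted from the dentate gyrus, the part of the hippocampus in which new granule neurons form in adult mice. The mice were 6 to 7 weeks old and carried a reporter in which the red fluorescent protein DsRed marks cells expressing doublecortin (Dcx), a microtubule-associated protein of neuroblasts and immature neurons. The study set 2 libraries from Fmr1 knockout mice against 2 libraries from wild type littermates. Fmr1 encodes FMRP, an RNA-binding protein that regulates translation and whose loss underlies fragile X syndrome. The wild type libraries held 5478224 and 7213759 counts, and the knockout libraries held 5662429 and 6702841 counts. Replicates of a genotype differed by more than counting noise, with a chi-square per degree of freedom of 41.6 between the wild type libraries and 58.0 between the knockout libraries, so neither pair held one library deposited again. That comparison does not show whether replicates came from separate animals. Of 52636 genes in the table, 14673 had enough counts to be tested, and 12742 of these were protein coding.

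The first question was whether the targeted transcript differed between the genotypes. Fmr1 (ENSMUSG00000000838.17, chromosome X, 68678541 to 68717963, GRCm38) lay at 73.1 and 91.6 CPM (counts scaled to the size of the library) in the wild type libraries, a mean of 82.3 ± 13.1 (SD, n = 2). It lay at 43.4 and 29.7 CPM in the knockout libraries, a mean of 36.5 ± 9.71 (SD, n = 2). Both knockout libraries were below both wild type libraries, the direction the labels imply, and 254 and 183 counts of the gene remained in them. The log2 fold change was -1.17 with a standard error of 0.36. Its unadjusted p was 0.0134 and its adjusted p was 0.9999 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so Fmr1 itself was not called.

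Huntingtin and 3 genes of mitochondrial fusion had been chosen to be reported whatever their result, and none of them passed the test. Mfn2, an outer-membrane fusion GTPase, had 149.4 ± 1.19 CPM in wild type and 115.2 ± 5.22 CPM in knockout libraries (SD, n = 2 each), a log2 fold change of -0.37 with a standard error of 0.27. Mfn1, its close relative, had 141.9 ± 3.59 and 115.5 ± 8.74 CPM (SD, n = 2 each), a log2 fold change of -0.30 with a standard error of 0.27. For both mitofusins each knockout library lay below each wild type library. Opa1, which fuses the inner membrane, had 119.5 ± 0.988 and 124.9 ± 10.7 CPM, and Htt had 202.3 ± 21.5 and 210.3 ± 12.6 CPM (SD, n = 2 each). Their log2 fold changes of 0.06 were smaller than their standard errors of 0.27.

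**Figure D1:**
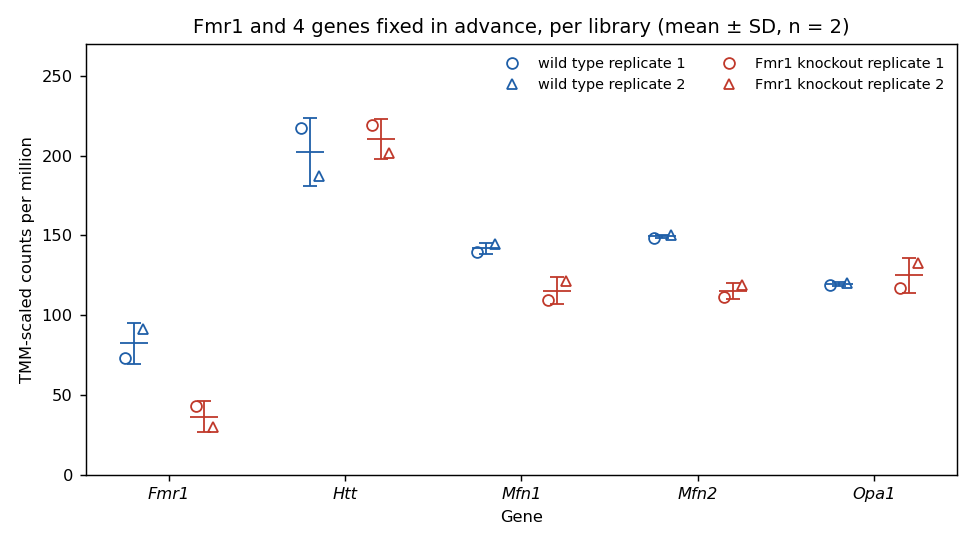
TMM-scaled CPM of Fmr1, Htt, Mfn1, Mfn2 and Opa1 in each library, with wild type in blue, Fmr1 knockout in red, circles for replicate 1, triangles for replicate 2, and bars for the mean ± SD of 2 libraries. Fmr1 sits at 73.1 and 91.6 in wild type and at 43.4 and 29.7 in knockout libraries, and the mitofusins also sit lower in both knockout libraries, while none of the 5 genes passed the test.

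Across the transcriptome no gene was called between Fmr1 knockout and wild type cells. The counts were 0 higher and 0 lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05, 69 genes were higher and 85 were lower, fewer than the 733.65 that chance gives for 14673 genes. That share of 1.05% depended on single libraries: it was 6.57% (1053 genes) without knockout replicate 1, 3.76% (603 genes) without knockout replicate 2, 0.356% (57 genes) without wild type replicate 1 and 1.33% (213 genes) without wild type replicate 2, with 0 genes called in each. DESeq2 also called 0 genes in either direction, with 158 higher and 222 lower at an unadjusted p under 0.05, and limma voom called 0, with 42 higher and 45 lower. Both knockout libraries lay above both wild type libraries for 1735 genes (11.8%) and below them for 2015 genes (13.7%), where chance gives 16.7% each way. These chance figures assume libraries without the difference between replicate numbers described below. That difference enters the spread in this fit, so falling below them does not show that the genotypes were alike. With the replicate number as a block, 5.30% of genes had an unadjusted p under 0.05 (edgeR).

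The higher side was ranked by unadjusted p among genes with both knockout libraries above both wild type libraries. Its first 8 genes were P2ry2, Lrfn1, C1qb, Tmem145, Unc119b, Ppp1r13l, Stx1a and Heatr6. None was called. Their separation between genotypes was required by the rule, and the size of their differences is partly a product of picking by p. Stx1a, the syntaxin of the presynaptic release machinery, had 18.6 ± 3.02 CPM in wild type and 44.1 ± 4.11 CPM in knockout libraries (SD, n = 2 each), a log2 fold change of 1.25 with a standard error of 0.41. Lrfn1, a synaptic adhesion molecule, had 11.1 ± 1.58 and 31.9 ± 1.16 CPM (SD, n = 2 each), a log2 fold change of 1.52 with a standard error of 0.47. Unc119b had 35.3 ± 1.99 and 70.7 ± 0.769 CPM, and Heatr6 had 24.9 ± 0.33 and 56.5 ± 16.4 CPM (SD, n = 2 each). Tmem145 had 12.5 ± 1.99 and 35.2 ± 8.92 CPM, and Ppp1r13l, an inhibitor of p53, had 1.77 ± 0.347 and 12.01 ± 2.73 CPM (SD, n = 2 each). P2ry2, a nucleotide receptor, was counted 2 times in wild type and 120 times in knockout libraries. The ratio of these pooled counts, relative to the summed scaled library sizes, was 64.1, with an exact 95% interval of 17.4 to 535 that covers counting error only. C1qb, a complement subunit made by microglia, had 0.339 and 2.16 CPM in wild type and 12.3 and 15.9 CPM in knockout libraries. Its partner subunit C1qa, chosen after its values were seen, did not share that separation and had 6.44 and 2.16 CPM in wild type and 0.342 and 3.40 CPM in knockout libraries.

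On the lower side the rule required both knockout libraries below both wild type libraries. It gave the 8 genes Pygm, Dclre1a, Selenop, Cpped1, Enoph1, Fmr1, Cetn2 and Crym, again none of them called. Selenop, the carrier of selenium in plasma, had 95.4 ± 21.3 CPM in wild type and 44.7 ± 4.09 CPM in knockout libraries (SD, n = 2 each), a log2 fold change of -1.09 with a standard error of 0.32. Pygm, a glycogen phosphorylase, had 17.6 ± 3.81 and 2.91 ± 0.244 CPM (SD, n = 2 each), a log2 fold change of -2.59 with a standard error of 0.71. Crym, which binds thyroid hormone, had 47.0 ± 12.5 and 19.6 ± 3.50 CPM (SD, n = 2 each). Dclre1a, a nuclease of DNA crosslink repair, had 22.4 ± 0.504 and 4.69 ± 1.82 CPM, and Cetn2, a centriole protein encoded on the X chromosome at 72913532 to 72918411, had 15.7 ± 1.48 and 3.16 ± 0.117 CPM (SD, n = 2 each). Enoph1, an enzyme of methionine salvage, had 35.1 ± 10.1 and 11.6 ± 0.0359 CPM, and Cpped1 had 42.2 ± 8.80 and 15.4 ± 2.25 CPM (SD, n = 2 each). The spread between replicates limited these comparisons. The common biological coefficient of variation was 0.538, and at the spread fitted here simulated 2-fold changes were called for 0 of 200 genes and simulated 4-fold changes for 47.5% of 200.

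Groups of genes gave the same answer: of 39 lists of pathways, complexes and cell types tested with camera, 0 were called higher and 0 lower. The lists held no gene called over all genes tested, and none when p was adjusted over the list alone. At an unadjusted p under 0.05, 1 list lay on the higher side and 2 on the lower side. With an estimated correlation the adjusted p was 0.992 for each list, and fry called 0 lists in its directional and in its mixed test. The smallest p among the mixed tests, which ask for change in either direction, belonged to the interferon response list (unadjusted p 0.00131, adjusted p 0.0513, fry). The statements on lists below give how many members had estimates above or below 0, with no list passing the test. Medians are log2 fold changes, knockout minus wild type.

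Mitochondrial genes were measured in 8 lists. Nuclear-encoded subunits of respiratory complex I, the NADH dehydrogenase, gave the smallest p among the lists in the camera test with its preset correlation. Of 36 subunits tested, 26 had estimates below 0 and the median was -0.18, with an unadjusted p of 0.00405 and an adjusted p of 0.158 (camera). In 12 of the 36 both knockout libraries lay below both wild type libraries, and the medians were -0.18 among replicate 1 libraries and -0.44 among replicate 2 libraries. Of 38 nuclear-encoded subunits of complexes II to V, 28 had estimates below 0 with a median of -0.15 and an adjusted p of 0.387 (camera). After a correction for gene length and GC content the smallest adjusted p of any list was 0.883. Among examples chosen after their values were seen, Ndufb11 had 45.3 ± 10.1 CPM in wild type and 27.6 ± 0.796 CPM in knockout libraries, and Cox6c had 126.7 ± 7.98 and 89.1 ± 13.9 CPM (SD, n = 2 each). Atp5b, the most abundant subunit of complexes II to V, had an estimate within its standard error of 0, at 624.2 ± 20.1 and 653.6 ± 62.2 CPM (SD, n = 2 each).

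Of 13 mRNAs of the mitochondrial genome, 7 were tested, and all 7 had estimates above 0, with a median of 0.29. Their estimated correlation was 0.999, so their shared sign is close to a single observation. The medians were 0.00 among replicate 1 and 0.37 among replicate 2 libraries. The most abundant, mt-Co1, had 2565 and 5857 CPM in wild type and 2793 and 7634 CPM in knockout libraries, so the difference between replicate numbers was larger than that between genotypes. Mitochondrial ribosomal proteins had 25 of 47 estimates below 0 (median -0.06), and Mrps5 had 67.4 ± 9.42 and 64.5 ± 3.003 CPM (SD, n = 2 each). Genes of mitochondrial fusion had 9 of 15 estimates above 0, with a median of 0.05 and a mean of -0.12. Fission genes had 8 of 14 below 0 (median -0.08), among them Inf2, a formin, at 139.5 ± 21.8 and 113.5 ± 5.65 CPM (SD, n = 2 each). Genes for moving mitochondria along axons had 11 of 16 above 0 (median 0.16), with the kinesin Kif5a at 548.6 ± 279.7 and 815.4 ± 586.2 CPM (SD, n = 2 each). Regulators of mitochondrial biogenesis had 12 of 18 below 0 (median -0.07), and Polg, the mitochondrial DNA polymerase, had 124.9 ± 51.9 and 119.5 ± 36.6 CPM (SD, n = 2 each). The adjusted p (camera) of these 6 lists was at least 0.537.

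In metabolism outside the respiratory chain, 14 of 18 genes of the TCA cycle had estimates below 0 (median -0.09), and so had 9 of 17 glycolytic genes (median -0.09). Aldoc, the aldolase of astrocytes, had 1013 ± 274 and 837 ± 396 CPM (SD, n = 2 each). Antioxidant enzymes were split 10 against 10 (median -0.01), with Prdx6 at 256.2 ± 36.2 and 236.9 ± 107 CPM (SD, n = 2 each). One of them, Nqo1, a quinone reductase named after its values were seen, had 6.78 and 5.62 CPM in wild type and 0.342 and 0 CPM in knockout libraries, with an unadjusted p of 0.029 that did not pass adjustment. Cholesterol synthesis had 12 of 22 estimates above 0 (median 0.01), with medians of 0.19 among replicate 1 and -0.37 among replicate 2 libraries, and Hmgcs1 had 274 ± 106 and 233 ± 3.53 CPM (SD, n = 2 each).

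Messenger RNAs reported to be bound by FMRP had estimates above 0 for 38 of 48 members, with a median of 0.06 and an adjusted p of 0.537 (camera). The medians were 0.05 among replicate 1 and 0.10 among replicate 2 libraries. After the correction for gene length and GC content the list's unadjusted p went from 0.0894 to 0.492 (camera). Scaled by library size alone, its median was 0.003. Camk2a, a kinase of the postsynaptic density that stands in this list, in the glutamatergic list and among the mature granule neuron markers, had 774 and 1777 CPM in wild type and 819 and 2954 CPM in knockout libraries, so it too varied mainly with replicate number. Map2, a dendritic microtubule protein chosen after its values were seen, had 834 ± 177 and 1092 ± 493 CPM (SD, n = 2 each). FMRP's relatives and partners had 8 of 12 estimates below 0 (median -0.04), Fmr1 among them. Cyfip2, an FMRP-interacting protein of the WAVE complex, had 409.8 ± 59.7 and 407.0 ± 121 CPM (SD, n = 2 each). Cytosolic ribosomal proteins had 36 of 53 estimates below 0 (median -0.15, adjusted p 0.537, camera), although the most abundant, Rps3, lay at 344.5 ± 79.9 and 345.0 ± 4.41 CPM (SD, n = 2 each). Translation regulators and mTOR signalling had 12 of 21 above 0 (median 0.06), with the initiation factor Eif4g1 at 316.7 ± 9.16 and 368.3 ± 104 CPM (SD, n = 2 each).

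Among synaptic genes, 19 of 24 members of the presynaptic vesicle machinery had estimates above 0 (median 0.14, adjusted p 0.537, camera). In 6 of them both knockout libraries lay above both wild type libraries and in 0 below, and Stx1a was the member with an unadjusted p under 0.05. The list medians were 0.02 among replicate 1 and 0.29 among replicate 2 libraries, and without knockout replicate 2 the list's direction turned to lower (unadjusted p 0.617, camera). Syt11, the most abundant, had 1217 ± 163 and 1319 ± 27.4 CPM (SD, n = 2 each). Glutamate receptors and postsynaptic density genes had 18 of 29 above 0 (median 0.09), with medians of -0.11 among replicate 1 and 0.13 among replicate 2 libraries. Voltage-gated channels had 20 of 31 above 0 (median 0.09), and Cacna1e, a calcium channel, had 575.0 ± 2.69 and 566.0 ± 5.92 CPM (SD, n = 2 each). Genes of GABA receptors and their synapse had 11 of 20 below 0 (median -0.07), and Gabbr1, a metabotropic GABA receptor, had 567.0 ± 18.4 and 585.8 ± 63.5 CPM (SD, n = 2 each).

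Genes of neuronal growth and of developmental signalling had estimates mostly above 0. The counts were 21 of 31 for dendrite, axon and cytoskeleton growth (median 0.13), 21 of 31 for axon guidance and adhesion (median 0.07), 16 of 24 for Wnt signalling (median 0.13) and 10 of 18 for Notch signalling (median 0.02). Their adjusted p values (camera) ran from 0.537 to 0.66. Map1b, a microtubule protein of growing axons, had 1268 ± 290 and 1187 ± 249 CPM and the adhesion molecule Ncam1 had 768 ± 54.0 and 739 ± 39.0 CPM (SD, n = 2 each). Tcf4, which the Wnt list holds by its symbol although it encodes the helix-loop-helix factor E2-2 and not the Wnt effector Tcf7l2, had 1130 ± 298 and 1140 ± 255 CPM, and the receptor Notch2 had 287 ± 202 and 245 ± 183 CPM (SD, n = 2 each).

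Transcripts of neurons and of glia were abundant in all 4 libraries. Dcx itself, the gene behind the sort, had 330 and 166 CPM in wild type and 456 and 211 CPM in knockout libraries. The astrocytic glutamate transporter Slc1a2 had 5454 and 5110 CPM in wild type and 5853 and 4771 CPM in knockout libraries. Neuroblast and immature granule neuron markers had 16 of 22 estimates above 0 (median 0.13, adjusted p 0.537, camera), and Nfib, the most abundant, had 960 ± 414 and 995 ± 501 CPM (SD, n = 2 each). Cell cycle genes had 18 of 30 above 0 (median 0.20), but the medians were 0.28 among replicate 1 and -0.23 among replicate 2 libraries, and Mki67, a marker of dividing cells, had 103 and 43.9 CPM in wild type and 149 and 36.3 CPM in knockout libraries. Mature granule neuron markers had 10 of 17 below 0 (median -0.02). Radial glia-like stem cell and astrocyte markers had 16 of 23 below 0, with a median of -0.27 and an adjusted p of 0.537 (camera), and medians of -0.11 and -0.55 among replicate 1 and replicate 2 libraries. Markers of GABAergic interneurons had 7 of 10 above 0 (median 0.22, unadjusted p 0.0387, adjusted p 0.503, camera), with Gad1, which makes GABA, at 66.2 ± 5.15 and 79.1 ± 26.6 CPM (SD, n = 2 each).

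Oligodendrocyte lineage transcripts were abundant and differed between libraries of the same genotype. Pdgfra, a receptor of oligodendrocyte precursors that also stands in the fibroblast list, had 132 and 1186 CPM in wild type and 133 and 1485 CPM in knockout libraries. Oligodendrocyte markers had 9 of 14 estimates above 0 (median 0.12) and precursor markers had 12 of 14 (median 0.31), with Tnr at 1154 ± 952 and 1246 ± 813 CPM (SD, n = 2 each). The result for these lists with the preset correlation depended on single wild type libraries. Without wild type replicate 2, oligodendrocyte markers passed as higher (adjusted p 4.8e-06, camera) and so did precursor markers (adjusted p 0.00696). Without wild type replicate 1, oligodendrocyte markers passed as lower, microglia and macrophage markers passed as lower and neuroblast markers passed as higher, each with an adjusted p of 0.0366 (camera). With an estimated correlation none of these lists was called. That form of the test could hardly call a list with so few libraries, so its lack of calls does not decide the matter. In the fit to all libraries the estimated correlation was 0.959 for oligodendrocyte and 0.965 for precursor markers.

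Markers of other cell types lay at lower levels, and some had counts mainly in wild type replicate 2. Named after their values were seen, endothelial Cldn5 had 9 and 46 counts in wild type and 0 and 1 in knockout libraries. Microglial C1qc had 0 and 50, then 0 and 1, and the hemoglobin gene Hbb-bs had 1 and 105, then 0 and 0. C1qa (38 and 15, then 2 and 21) and C1qb (2 and 15, then 72 and 98) did not share this. Microglia and macrophage markers had 7 of 12 estimates below 0 (median -0.46), with medians of 0.49 among replicate 1 and -0.33 among replicate 2 libraries. Endothelial and mural cell markers had 11 of 17 below 0 (median -0.16), with Bsg at 86.4 ± 17.7 and 77.6 ± 5.57 CPM (SD, n = 2 each). Rgs5, a pericyte gene named after its values were seen, was the member with the smallest p, at 46.4 ± 30.3 and 17.7 ± 1.60 CPM (SD, n = 2 each). Fibroblast and meningeal markers had 3 of 5 above 0 (median 0.29). Too few ependymal and choroid plexus or red blood cell markers were measured for a test. Foxj1, of ciliated cells, had 9.96 ± 5.46 and 9.81 ± 0.34 CPM (SD, n = 2 each).

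**Figure D2:**
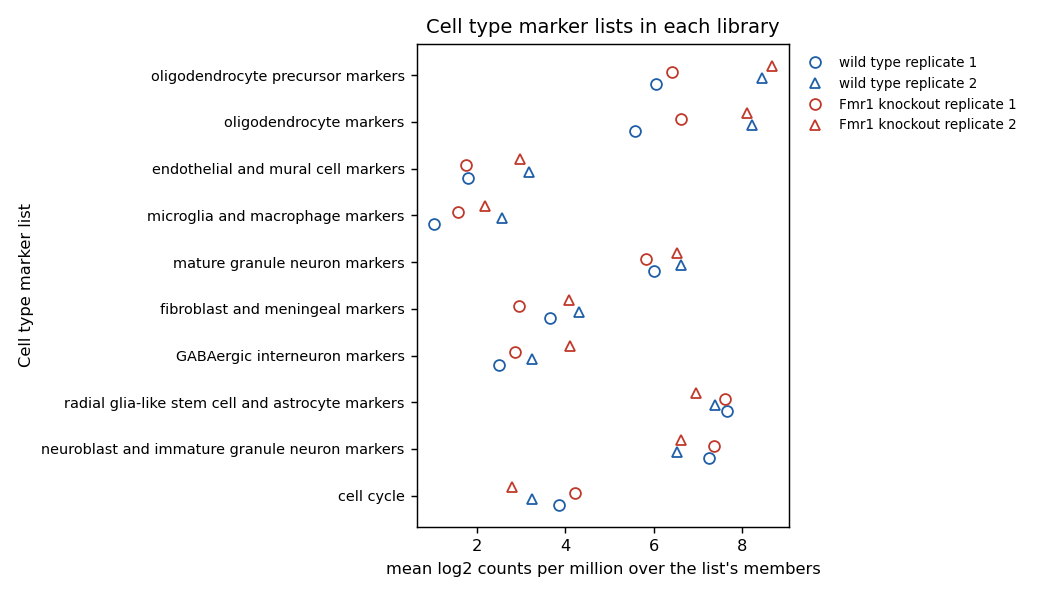
Mean log2 CPM over the tested members of each cell type marker list (horizontal axis) in each library, with wild type in blue, Fmr1 knockout in red, circles for replicate 1 and triangles for replicate 2. In both genotypes the replicate 2 library lies to the right for oligodendrocyte and precursor markers. It lies to the left for neuroblast markers, cell cycle genes, and radial glia-like stem cell and astrocyte markers. This separation follows the replicate number and not the genotype.

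Lists of cell state gave no call either. Immediate early genes, which neuronal activity induces, had 13 of 19 estimates above 0 (median 0.08), and Jun had 177.0 ± 7.72 and 151.3 ± 37.4 CPM (SD, n = 2 each). Heat shock and unfolded protein response genes had 14 of 22 below 0 (median -0.15), with the chaperone Hsp90ab1 at 1339 ± 147 and 1215 ± 43.3 CPM (SD, n = 2 each). Genes of apoptosis and p53 targets had 13 of 19 above 0 (median 0.09), with Diablo at 97.1 ± 23.8 and 103.1 ± 12.2 CPM (SD, n = 2 each). Interferon response genes had 9 of 12 above 0 (median 0.10), with Ifi27 at 48.7 ± 13.2 and 52.4 ± 14.5 CPM (SD, n = 2 each). Autophagy and mitophagy genes had 14 of 23 below 0 (median -0.05), with Gabarapl1 at 282 ± 26.1 and 263 ± 94.6 CPM (SD, n = 2 each).

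The direction of many lists was not stable. In 26 of the 39 lists the camera direction turned when 1 library was left out, reported FMRP targets among them, and in 13, complex I and complexes II to V among them, it did not. In 14 lists the medians among replicate 1 and among replicate 2 libraries differed in sign. In 11 lists the median, the mean and the camera test differed in sign: mitochondrial fusion, fission and biogenesis, cholesterol synthesis, translation and mTOR signalling, microglia, fibroblasts, immediate early genes, apoptosis, interferon response and autophagy. In 7 lists the median lay so close to 0 that the shift of all genes between scalings changed its sign: mitochondrial fusion, antioxidant enzymes, cholesterol synthesis, translation and mTOR signalling, Notch signalling, mature granule neuron markers and immediate early genes.

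**Figure D3:**
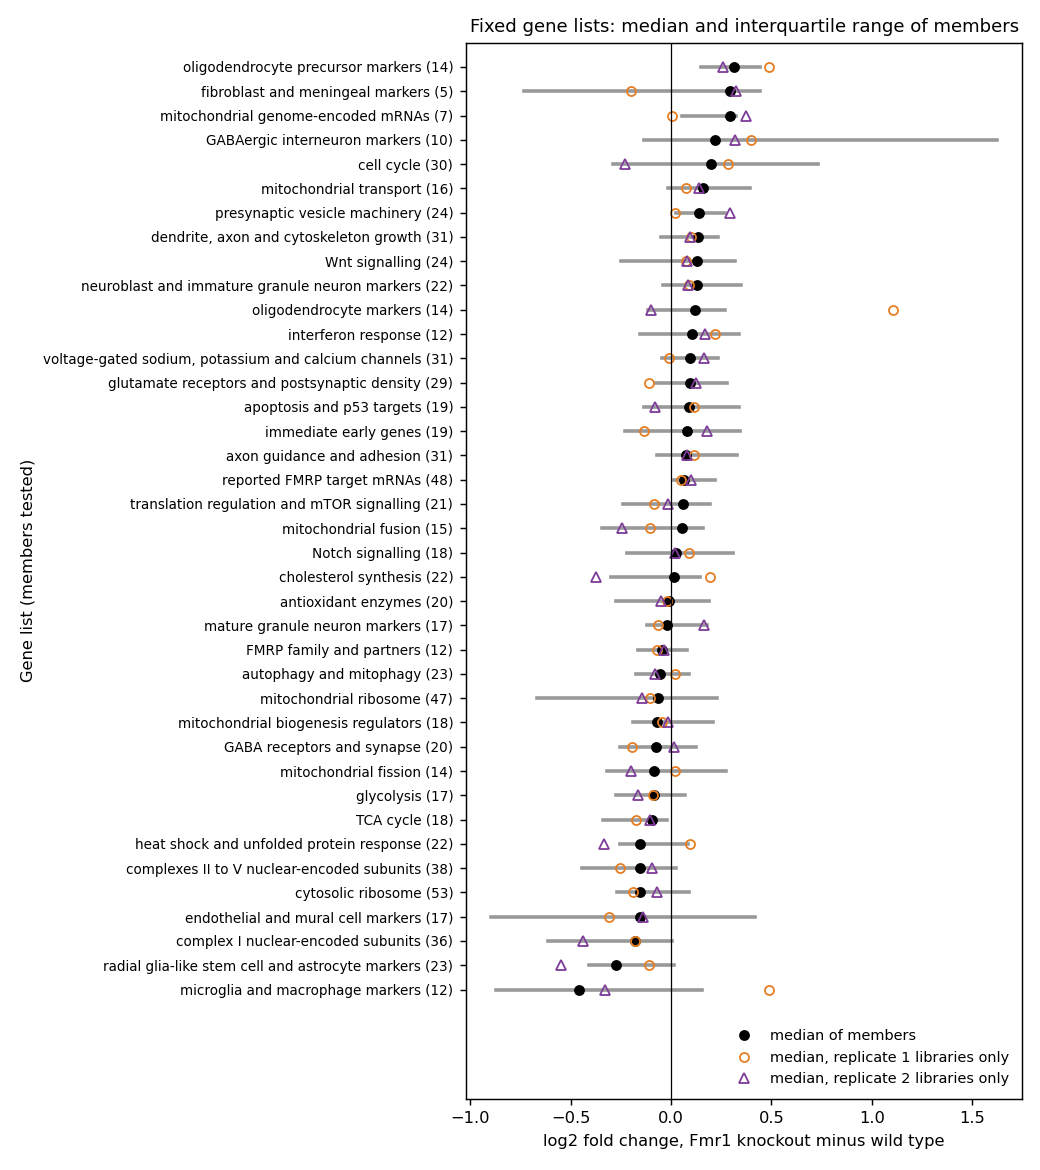
Median log2 fold change (knockout minus wild type, horizontal axis) of each of the 39 tested gene lists as a black point, with the interquartile range of its members as a grey bar and the medians among replicate 1 libraries (orange circles) and replicate 2 libraries (purple triangles). Complex I subunits have a median of -0.18, reported FMRP targets one of 0.06, and the oligodendrocyte list ranges from 1.11 among replicate 1 to -0.10 among replicate 2 libraries; no list passed the test.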

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

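Alternatives that leave out rRNA-like loci, join the block with the length and GC correction, or leave out a library with the list correlation estimated were chosen after the data were seen. No gene was called in either direction by edgeR, DESeq2 or limma voom, under any scaling, filter or threshold tried, or without any single library, with 1 exception. With the replicate number as a block, 7 genes were called higher and 3 lower. Named after their values were seen, those higher include Gm23935, Gm26917, mt-Rnr2, CT010467.1, Gpr17 and Mb21d2, among them 3 rRNA-like loci and a mitochondrial rRNA, and those lower are Oaf, Htra1 and Pdcl3. The block adds a term to a fit of 4 libraries, which leaves little to estimate the spread from. Some calls rest mainly on 1 pair. Gm26917 had 18471 and 43119 counts in wild type and knockout replicate 1, but 40778 and 40693 in replicate 2. Htra1 had 2569 and 2194 counts in replicate 1, and 2365 and 796 in replicate 2. The labels do not say that a replicate number marks a litter or batch, and the libraries share only a number. Differences between replicate 2 and replicate 1 correlated at 0.364 across genes between the genotypes, and differences between genotypes at 0.0495 between the numbers. The share of genes at an unadjusted p under 0.05 went from 1.05% to 5.30% with the block. The log2 fold change of Fmr1 was -1.19 with the block (adjusted p 0.0971) and lay between -1.16 and -1.21 in the other fits to all libraries. It lay between -0.937 and -1.47 with 1 library left out, and it was not called in any of them. The smallest gene-level adjusted p ran from 0.673 to 0.9999 over the alternatives other than the block. No list was called with the block, with or without the length and GC correction, nor in the other list tests that used all libraries. When 1 library was left out, the number of lists called ranged from 0 to 2 higher and from 0 to 2 lower, all of them without one of the wild type libraries and at the preset correlation. An estimated correlation could hardly give a call in those fits, so its lack of calls there does not decide the matter. Such fits leave 1 library in a genotype, which is assumed to vary like the others. For the 57 named genes other than Fmr1, 779 values over 15 alternatives kept their sign and stayed uncalled, 74 changed sign without a call, and 1, with the block, became a call. With 2 libraries per genotype at this spread, changes of 2-fold were out of reach of the gene test, so the counts of 0 do not show that expression was alike.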

Other observations

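The test of cell composition for the replicate number was chosen after the result was seen; those of respiratory subunits and of the genes around Fmr1 were chosen before theirs.

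The libraries numbered 1 and 2 differed in both genotypes, though not by like amounts, and the single genes given for this were chosen after their values were seen. The first principal component, 54.8% of the variance, put the replicate 1 libraries at -55.9 (wild type) and -66.2 (knockout) and the replicate 2 libraries at 24.0 and 98.1. In the edgeR fit with both terms, 1038 genes were higher and 569 lower in the libraries numbered 2 at an adjusted p under 0.05. That is the fit with the block, which leaves little to estimate the spread from, so these counts are uncertain too. Oligodendrocyte precursor markers had a median log2 difference of 2.44 and oligodendrocyte markers one of 1.68, with Olig2, a transcription factor of the lineage, at 22.0 and 257 CPM in wild type and 47.0 and 406 CPM in knockout replicates 1 and 2. Neuroblast markers had a median of -0.88 and cell cycle genes one of -0.94. Among markers of new neurons, Sox11 had 662 and 274 CPM in wild type and 854 and 350 CPM in knockout replicates 1 and 2, and Calb2, the calretinin of immature granule neurons, had 170 and 53.6 CPM and 168 and 88.5 CPM. Mature granule neuron markers had a median of 0.64. The mitochondrial transcript mt-Nd6, which lies antisense to its neighbours and whose counting by strand is unknown, had 29.0 and 552 CPM in wild type and 29.7 and 1052 CPM in knockout replicates 1 and 2. The repeat-like locus Gm26870 went the other way, at 644 and 0.864 CPM and 710 and 5.35 CPM.

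The replicate number is not a group of the study, so the design gave no biological explanation to test, and the cell makeup of the libraries is weighed here. A loss of sorted neuroblasts alone that raises every other cell type alike is argued against by the radial glia-like stem cell and astrocyte markers. Their median was -0.6572 with a standard error of 0.17 over members, which is not an error between libraries. Oligodendrocyte, precursor and endothelial markers lay above 0, and so did microglia and macrophage markers (median 1.10, standard error 0.49 over members). The list mixes stem cell with astrocyte genes, so it cannot weigh a loss of neuroblasts together with stem cells. The source of the higher oligodendrocyte lineage transcripts in the libraries numbered 2 stays open; a sort for Dcx-DsRed should remove such cells.

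Nuclear-encoded respiratory subunits had the smallest p values on the lower side in the camera test with its preset correlation, and the pattern remains a hypothesis because no list was called and because these 2 lists were picked from 39 by their p. Of 74 subunits, 54 had estimates below 0, with a median of -0.15 (bootstrap 95% interval -0.30 to -0.06). The bootstrap resampled genes measured in the same 4 libraries, so its intervals carry no error between libraries. In 24 subunits (32.4%) both knockout libraries lay below both wild type libraries, against 13.7% over all tested genes. Because the lists were picked by p, such an excess was partly built in. A single deviating library is argued against, since the median was at or below -0.1878 with any library left out. Those medians are differences of mean log2 CPM and not edgeR estimates, so their size cannot be compared with -0.15. A trend with gene length and GC content may account for much of it: after its removal the median was -0.06062 with an interval of -0.19 to 0.06. Over 10000 random lists alike in expression level and length, but not matched for GC content, the median was -0.04. Level and length alone thus gave a smaller shift than the -0.15 of the subunits. Chance among the lists and genotype both stay open for what remains.

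Cetn2, which lies within 10 Mb of Fmr1 on the X chromosome, was among the genes with the smallest p, which raised the question of a flanking segment of another strain carried with the targeted allele. Leaving out Fmr1 and Cetn2, both knockout libraries lay outside both wild type libraries on the same side for 18 of 76 genes (23.7%) within 10 Mb and for 89 of 395 other X genes (22.5%). The two-sided Fisher's exact p was 0.8812. A segment in which few genes differ in expression could not be seen by this count, and the deposited counts hold no sequence variants. Such a segment and the loss of Fmr1 therefore cannot be told apart for Cetn2. Chance stays open too, since Cetn2 was not called and was picked by its p.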
